A study of Caenorhabditis elegans with 41 samples.

How the data were processed

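Whole single worms were profiled on 1-colour Agilent arrays, 1 worm per array. Per the labels' protocols, total RNA of each snap-frozen worm was purified on magnetic beads and amplified as a whole transcriptome with the WTA2 kit, and the double-stranded cDNA was labelled with Cy3. Per the file headers, spots were read with Agilent Feature Extraction, which gave for each spot a mean intensity, a local background intensity and a background-subtracted, spatially detrended processed intensity that is not normalized between arrays. The flags for outliers, saturation and signal well above background are those of the same deposited scanner output. The deposited value table holds log2 values for all 45220 spots of each array. Its columns share one distribution (largest difference between quantiles 0.00175, median 8.632 in every column) and rank the spots of each array as mean minus background intensity does (rank correlation 1 on every array), so its scale and centring are known from the values, while the steps that made it are not given in the sources used here.

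Each array carries 43803 spots of worm probes and 1417 control spots. The worm spots hold 41570 probe names and 40942 distinct sequences of 60 bases, and the unit of every test was the distinct sequence, named by its first probe name. The main values were log2 of the processed intensity minus the array's 75th percentile over worm spots. Control spots and outlier-flagged spots were left out (0.183% of worm spots, 33 to 474 per array), spots of one sequence were averaged, and 771 values with no unflagged spot (0.0459%) were replaced by their batch mean. No worm spot was saturated. A probe counted as detected when well above background on at least 21 of 41 arrays, which left 38592 probes; 26205 were well above background on all arrays.

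The files repeat the probe name where a gene name would stand, and 0 of 41570 probe names matched the reference table of 46926 genes. The gene lists, the gene-name rule for named genes and the 2-probes-per-gene comparison chosen before the data were examined could therefore not be run as written. In their place each 60-base sequence was translated in its 3 forward frames, and 19 residues were compared with 29 query proteins written from general knowledge. A probe entered a family when at least 12 of 19 residues matched, or, for the collagen repeat, when at least 5 glycines stood in a row of residue triplets with no stop. The queries and limits were chosen after the probe sequences had been read and before any signal was viewed by family, so the families were not fixed before the data were examined. Against shuffled copies of each query (20 copies) the best match was 12 residues, reached by the long myosin query alone, and the opposite strand gave 0 matches, except 1 for the collagen repeat. Families with at least 5 detected probes were tested: vitellogenin (7), major sperm protein (26), collagen repeat (50), histone (61), ribosomal protein (18), myosin heavy chain (7), and actin, tubulin, ubiquitin and GAPDH (35). Homeodomain (4), heat shock chaperone (3) and ATP synthase beta (1) were too small to test, and no probe matched the nuclear receptor or elongation factor 1 alpha queries.

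Variation was the SD of residuals from batch means, divided by the SD expected at the probe's mean signal from a lowess curve with a span of 0.4. A probe was highly variable with a ratio above 1.5 over all batches and above 1 in each batch. Overlapping probe pairs shared at least 20 bases exactly, and their correlation was tested with 10000 one-sided shuffles of worms within batches. Families were tested against 10000 random lists matched on mean signal in 20 bins (two-sided). Correlations of scores used 100000 two-sided shuffles within batches, and the other settings of the component relations used 10000. The r without 2 worms leaves out those farthest from the median of the first score named or, in relations with a component, of the component. Associations with a score were limma slopes with batch as a covariate and a trended prior, leaving the family's own probes out, and batches were compared with limma's F-test. Fitted without a trend to the within-batch variances, the prior had an SD of 0.48 with 3.34 degrees of freedom. All adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. Refits across all probes were limited to 100 regroupings. By the rule for named items, probes were ranked by slope among those that passed with one sign in every batch; without gene names the first probe on each side is given for 2 scores.

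The alternatives chosen before the data were examined were normexp background correction with an offset of 50, quantile normalization, the authors' value table, no filter on dim probes or a filter on all arrays, array quality covariates, slide, each batch left out, Spearman correlation, a ratio threshold of 2, a robust SD, the extreme probes of 3 or more overlapping ones, and unscaled components. Scaling to the actin, tubulin, ubiquitin and GAPDH probes, removal of each array's trend over probe GC content, overlaps of at least 40 bases and leaving out batch 3 worms 2, 17 and 19 were added after the data had been seen. The slide follows from the array position recorded in the files; there were 13 slides, 3 in batch 1 and 5 in each of batches 2 and 3.

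Each procedure was tested on simulated data with known answers, although the first runs on the real files came before those tests were written. Of 200 probes given extra variation among 38592, 200 were called, with 73 others. Of 100 correlated pairs among 1100, 91 passed, with 7 others. Of 400 probes tied to a score among 38592, 399 passed, with 26 others, and of 200 probes shifted between batches among 38592, 162 passed, with 12 others. Simulated probes without a shared signal varied independently, whereas real probes covaried, so these counts of others do not carry over to the real data. There, shuffled vitellogenin and major sperm protein scores gave up to 2496 and 2899 probes, and random splits into batches up to 3510, although the median was 0 in each case. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, R 4.3.3, limma 3.58.1 and statmod 1.5.0.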

Results

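The transcripts of 41 individual N2 worms, the wild-type laboratory strain of the nematode Caenorhabditis elegans, were measured with 1 array per worm. All worms grew at 20 °C and were collected 46 h after hatching, near the last moult and the start of adult life. The labels place 9 worms in batch 1, 12 in batch 2 and 20 in batch 3, and give no treatment, so the question is which transcripts differ between individuals that share strain, age and temperature. The share of spots well above background lay between 0.743 and 0.871 in batch 1, between 0.788 and 0.869 in batch 2 and between 0.934 and 0.997 in batch 3. The number of arrays limits the precision of every value below. Any pair of worms of a batch had a correlation of at least 0.853 and at most 0.991 across the 38592 detected probes, and any pair from different batches at most 0.962, so no array was a copy of another. The labels do not say whether worms of a batch shared a culture. Probes are described by the protein family that their translated sequence resembles, since the files pair no probe with a gene, and a family is no gene name.

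Yolk and sperm transcripts differed in level between worms of one batch. The vitellogenin probes, for the yolk proteins that the adult intestine makes for the oocytes, had a mean log2 signal of 4.99 ± 0.42 (SD, n = 9) in batch 1, 3.87 ± 0.41 (SD, n = 12) in batch 2 and 5.12 ± 0.75 (SD, n = 20) in batch 3, relative to the 75th percentile of each array. The highest worm exceeded the lowest by 2.20-fold in batch 1, 2.56-fold in batch 2 and 7.42-fold in batch 3. The 26 major sperm protein probes, for the abundant cytoskeletal protein of nematode sperm, stood at 2.15 ± 0.67 (SD, n = 9), 3.37 ± 0.27 (SD, n = 12) and 4.03 ± 1.00 (SD, n = 20) in the same order. The highest worm exceeded the lowest by 4.65-fold in batch 1, 1.83-fold in batch 2 and 17.8-fold in batch 3. In batch 3, worm 2 stood at 0.88, worm 19 at 1.95 and worm 17 at 3.02, while the other 17 worms of that batch lay between 3.88 and 5.03. In the same order, the collagen-repeat probes spanned 3.17-fold, 2.67-fold and 2.76-fold and the histone probes 2.21-fold, 2.18-fold and 2.17-fold. The myosin probes spanned 1.89-fold, 1.97-fold and 4.35-fold, the 18 ribosomal protein probes 1.67-fold, 1.49-fold and 1.86-fold, and the actin, tubulin, ubiquitin and GAPDH probes between 1.39-fold and 1.61-fold.

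**Figure D1:**
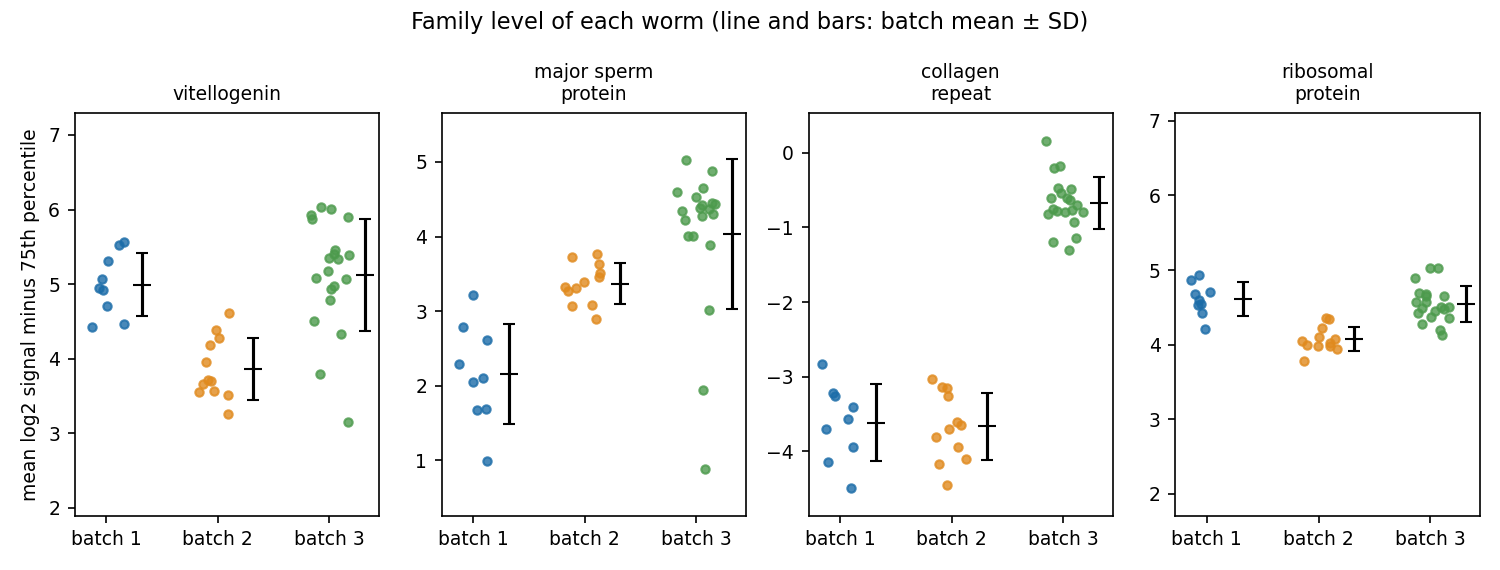
Mean log2 signal of the vitellogenin, major sperm protein, collagen-repeat and ribosomal protein probes in each worm, relative to the array's 75th percentile, by batch. Each point is 1 worm, and the line with bars gives the batch mean ± SD (n = 9, 12 and 20); all panels span the same number of log2 units. The major sperm protein signal of batch 3 worm 2 was 0.88, against 3.88 to 5.03 in the 17 batch 3 worms other than worms 2, 17 and 19.

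Variation beyond that of other probes of like brightness was found for vitellogenin, major sperm protein, collagen-repeat and histone probes. The ratio of a probe's within-batch SD to the SD expected at its mean signal had a median of 2.60 over the 26 major sperm protein probes. Of these, 20 met the criterion for high variability (a ratio above 1.5 over all batches and above 1 within each). With slide means removed 7 met it, although the median ratio was then 3.11, and all 26 met it with array quality covariates or without batch 2. All 7 vitellogenin probes met it, with a median ratio of 1.90. The collagen-repeat probes hold a glycine repeat like that of the cuticle collagens, which are made in pulses around each moult. The rule does not tell cuticle collagens from other proteins with such a repeat. The collagen-repeat median was 1.59, and 20 of 50 met the criterion (13 of the 27 well above background on all arrays). The histone probes had a median of 1.498, and 27 of 61 met it, but 14 without batch 1, 14 with the GC trend removed, 16 with slide means removed and 43 without batch 3. The adjusted permutation p against 10000 random lists matched on mean signal was 0.00315 for vitellogenin and 0.000467 for each of the other 3 families, the smallest that these lists can give there after adjustment over 7 families. Probes of a family moved together (mean pairwise r 0.81 for vitellogenin and 0.91 for major sperm protein, against 0.25 and 0.21 in matched lists). The random lists treat them as separate measurements, so these p-values overstate the evidence. The ribosomal protein probes had a median ratio of 0.88, and 0 of 18 were highly variable (3 without batch 3, 2 with array quality covariates; adjusted permutation p = 0.133). The actin, tubulin, ubiquitin and GAPDH probes had a median of 0.99 with 4 of 35 highly variable (2 to 6 over settings; adjusted permutation p = 0.897), and the muscle myosin heavy chain probes 1.31 with 1 of 7 (adjusted permutation p = 0.133). Without batch 3 worms 2, 17 and 19, a choice made after their levels were seen, the median ratio of the major sperm protein probes was 1.52 and 7 of 26 were highly variable, still with an adjusted permutation p of 0.00035.

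**Figure D2:**
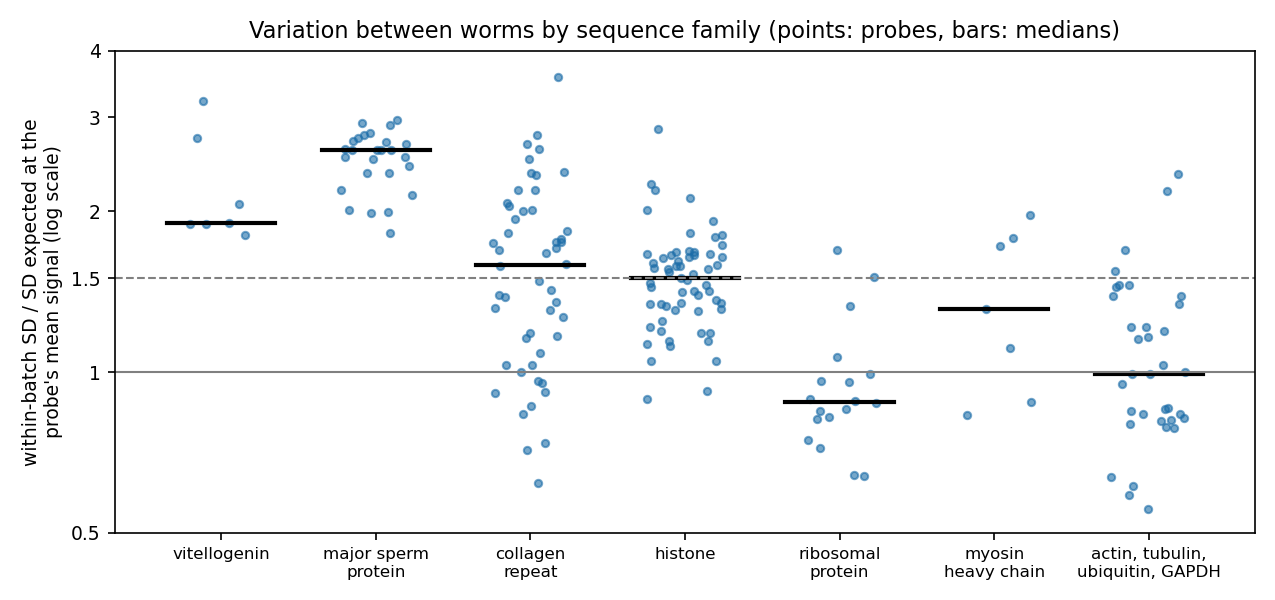
Ratio of the within-batch SD to the SD expected at the probe's mean signal, on a log scale, for each detected probe of 7 sequence families. Points are probes, thick bars are family medians, the solid grey line marks a ratio of 1 and the dashed line a ratio of 1.5. Medians were 1.90 for vitellogenin, 2.60 for major sperm protein, 1.59 for collagen repeat, 1.498 for histone and 0.88 for ribosomal protein.

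Over all detected probes, 4221 of 38592 (10.9%) were highly variable, and the median within-batch SD was 0.55 on the log2 scale. The SD ratio of a probe in one batch went with its ratio in another: Spearman's rho across probes, which are not independent replicates, was 0.41 between batches 1 and 2, 0.35 between batches 1 and 3 and 0.42 between batches 2 and 3. Spot error was small beside these differences. For the 205 detected probes printed as 11 spots, the median SD between spots of one array was 0.097, against 0.45 between worms of a batch, and spot error made up a median of 5.84% of the variance of a single spot. Of the pairs of probes whose sequences share at least 20 overlapping bases, and so cover shared transcript sequence, 2491 of 2541 were positively correlated over worms (one-sided permutation test, adjusted over pairs). Their median r was 0.89, against 0.02 for 19296 random pairs. Both probes of a pair share the amplification of that worm's cDNA and at least 20 bases of sequence. This comparison therefore covers spot error, and probe error only where it does not come from the shared bases.

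Members of a family moved together from worm to worm. The mean pairwise correlation of batch-centred values was 0.91 among major sperm protein probes and 0.81 among vitellogenin probes, with 0.21 and 0.25 in matched random lists. It was 0.53 among histone, 0.53 among ribosomal protein, 0.44 among myosin, 0.20 among collagen-repeat and 0.14 among actin, tubulin, ubiquitin and GAPDH probes. All 7 families passed (largest adjusted permutation p 0.0042). Probes of near-identical sequence, as in the major sperm protein and histone families, can bind each other's transcripts, which may raise these values and was not tested. Under quantile normalization and in the authors' value table the ribosomal protein value was 0.038 (adjusted permutation p = 0.792 and 0.773) and that of the actin, tubulin, ubiquitin and GAPDH probes 0.074 and 0.058 (0.0534 and 0.106), so neither passed there. The latter value also missed the threshold with the GC trend removed (0.094, adjusted permutation p = 0.203), and with scaling to those probes themselves it was -0.0087, below matched lists. With that scaling the myosin value of 0.42 did not pass (adjusted permutation p = 0.0536).

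Histone transcripts, which are in demand where DNA is being replicated, were higher in worms with more vitellogenin signal. A worm's score was the mean of its batch-centred and scaled values over a family, and 5 of the 21 pairs of scores were correlated after Benjamini-Hochberg adjustment. The vitellogenin and histone scores had r = 0.63 (permutation p = 3e-05, adjusted 0.000157) and rho = 0.68 (permutation p = 2e-05), with r = 0.94, 0.60 and 0.59 within batches 1, 2 and 3 and 0.67 without the 2 worms farthest from the median. Collagen-repeat and myosin scores had r = 0.67 and rho = 0.72 (both with permutation p = 1e-05, the smallest that 100000 shuffles can give, adjusted 7e-05). Within batches r was 0.85, 0.87 and 0.55, and without 2 worms it was 0.67. The tissue that the collagen-repeat transcripts came from was not tested. The vitellogenin and major sperm protein scores were not correlated at this threshold (r = -0.28, permutation p = 0.134, adjusted 0.234; rho = -0.28, permutation p = 0.0846). Their r was -0.48, 0.20 and -0.29 within batches 1, 2 and 3, and -0.29 without 2 worms.

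The other 3 correlated pairs joined histone, ribosome and actin, tubulin, ubiquitin and GAPDH scores and depended on the scaling of the arrays. The last family was not uniformly abundant. Mean log2 signals of its 35 probes ran from -6.04 to 6.11, and 4 were highly variable, although the median ratio was 0.99. Reference is used here only as a label for that family. Histone and ribosome scores had r = 0.74 (rho 0.76, both with permutation p = 1e-05, adjusted 7e-05; 0.92, 0.80 and 0.66 within batches; 0.77 without 2 worms). Ribosome scores had r = 0.71 with the actin, tubulin, ubiquitin and GAPDH scores (rho 0.73, both with permutation p = 1e-05, adjusted 7e-05; 0.76, 0.78 and 0.70 within batches; 0.71 without 2 worms). Histone scores had r = 0.61 with the same reference scores (permutation p = 5e-05, adjusted 0.00021; rho 0.60, permutation p = 7e-05; 0.82, 0.39 and 0.65 within batches; 0.58 without 2 worms). Under quantile normalization these values were 0.025, -0.098 and 0.31, and in the authors' value table -0.084, -0.15 and 0.25, none of them past the threshold. By a permutation of batch labels with Benjamini-Hochberg adjustment, slopes between scores differed between batches past the threshold for 0 of the 21 pairs, but for 1 pair with quantile normalization, 2 without batch 1 and 1 without batch 2. The unadjusted permutation p was under 0.05 for 5 pairs, and the lowest was 0.0024 for major sperm protein and collagen repeat (adjusted 0.0504).

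The main axis of variation between worms followed yolk, histone and, in part, sperm transcripts. The first principal component of batch-centred values held 23.7% of the variance, against at most 3.19% in 20 shuffled data sets, and the next 2 held 11.6% and 9.32%. Its direction was set so that worms with more vitellogenin signal score higher. It had r = 0.65 with the vitellogenin score (permutation p = 1e-04, adjusted over 45 relations 0.00112; rho 0.64, permutation p = 4e-05), with 0.75, 0.55 and 0.67 within batches and 0.61 without 2 worms. With the histone score r was 0.65 (permutation p = 1e-05, adjusted 0.000225; rho 0.62, permutation p = 5e-05), with 0.67, 0.64 and 0.71 within batches and 0.56 without 2 worms. With the major sperm protein score r was -0.59 (permutation p = 0.00107, adjusted 0.00602) and rho -0.50 (permutation p = 0.00095). It was -0.59 and -0.70 within batches 1 and 3, 0.03 within batch 2 and -0.45 without 2 worms. The 2 worms left out were those with the most extreme component values, batch 3 worms 17 and 19. Batch 3 worm 2, with the lowest sperm score, stayed in. In each other setting the component was taken anew, so its r is with a different axis. Without batch 3 worms 2, 17 and 19, where the component held 17.2%, the sperm r was -0.17 (adjusted permutation p = 0.55). Without batch 3 it was -0.10 (adjusted permutation p = 0.668). The pooled sperm relation thus depends on those worms being included, although batch 1, which holds none of them, had r = -0.59. The vitellogenin and histone relations had r = 0.63 and 0.64 without those 3 worms. With normexp, which keeps them, the sperm r was also not past the threshold (r = -0.36, adjusted permutation p = 0.0531). The collagen-repeat score was not related to the first component (r = -0.06, adjusted permutation p = 0.796). Its members moved together weakly (mean pairwise r 0.20), so this does not show that no collagen probe followed the component. The score passed with opposite signs with normexp (r = -0.38, adjusted permutation p = 0.045) and without batch 3 (r = 0.53, adjusted permutation p = 0.0339). It was related to the third component, with r = -0.60 (permutation p = 1e-05, adjusted 0.000225) and rho -0.60 (permutation p = 9e-05). That r was -0.93, -0.75 and -0.35 within batches and -0.57 without 2 worms. The third component also followed the raw signal level of the array, with r = -0.53 with the log2 raw 75th percentile (permutation p = 3e-05, adjusted 0.00045; rho -0.43, permutation p = 0.00311; -0.70, -0.90 and -0.34 within batches; -0.41 without 2 worms).

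**Figure D3:**
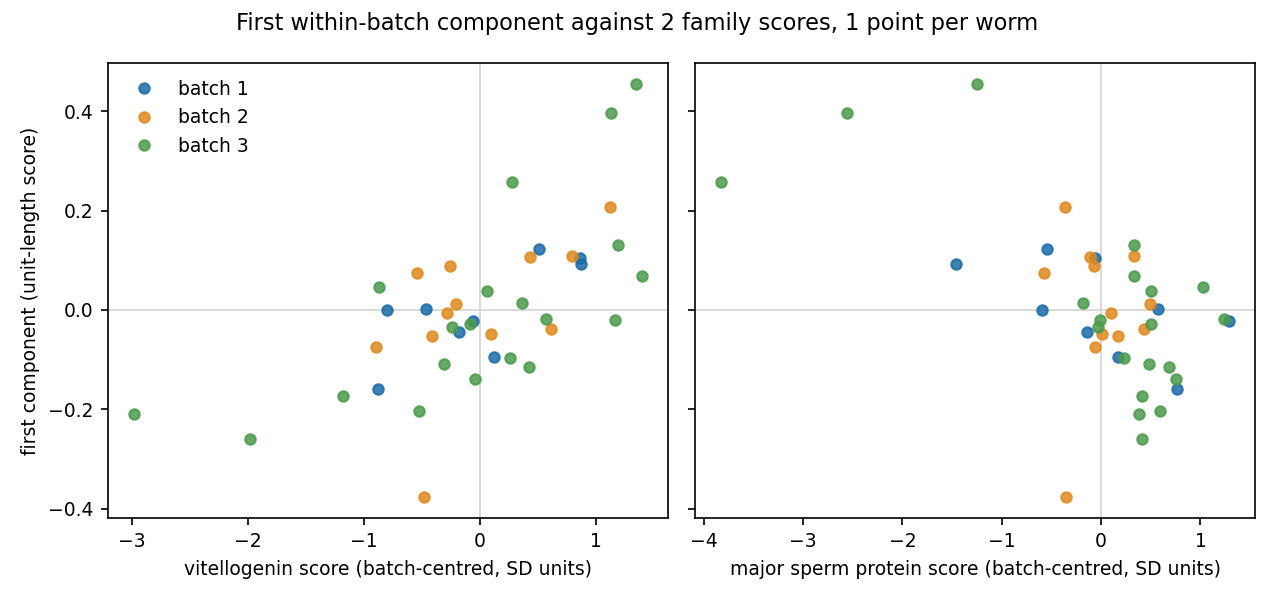
First within-batch component of each worm (unit-length score) against its vitellogenin score (left) and its major sperm protein score (right), both batch-centred and in SD units. Each point is 1 of 41 worms, with colours for the batches. The component has r = 0.65 with the vitellogenin score and -0.59 with the major sperm protein score, and the 3 batch 3 worms with the lowest sperm scores all have values of the component above 0.

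Most histone probes were associated with yolk. In limma fits with batch as a covariate, 12868 of 38585 probes were associated with the vitellogenin score, 7224 higher and 5644 lower. Of the 61 histone probes, 50 were higher and 2 lower (53 and 2 when adjusted over the list alone), with a median slope of 0.26 log2 units per unit of score. Of the 26 major sperm protein probes, 0 were higher and 2 lower in this limma fit, and of the 50 collagen-repeat probes 4 were higher and 4 lower. Of the ribosomal protein probes, 5 of 18 were higher. The steepest probe that kept its sign in every batch was CE0208_04225 on the rising side, with a slope of 1.61 ± 0.22 (SE, limma adjusted p = 3.44e-06), and CE0208_34449 on the falling side, with -2.46 ± 0.29 (SE, limma adjusted p = 2.72e-07). None of 100 shuffles of the score within batches gave as many probes, and the highest gave 2496. With slide means removed the count was 1463 in the same limma test (9468 at an unadjusted p under 0.05, in place of 16476), and without batch 3 worms 2, 17 and 19 it was 6616.

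The major sperm protein score was associated with 10656 of 38566 probes, 4465 higher and 6191 lower. Of the other families, 2 histone probes were higher and 3 lower, 1 vitellogenin probe was lower, 3 collagen-repeat probes were higher, and 8 of the 35 actin, tubulin, ubiquitin and GAPDH probes were higher and 4 lower. CE0208_34471 had the largest positive slope among probes of one sign in all batches, 1.70 ± 0.29 (SE, limma adjusted p = 1.25e-05), and CE0208_03949 the largest negative, -0.83 ± 0.20 (SE, limma adjusted p = 0.00119). The highest of 100 shuffles gave 2899 probes. Without batch 3 worms 2, 17 and 19, 2373 probes were associated in limma, 1960 higher and 413 lower, and without batch 3 there were 1195, 1183 higher and 12 lower.

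Many of the highly variable probes were higher in worms with more sperm signal or lower in worms with more yolk signal. Of the 4221 highly variable probes, 1775 were higher with the major sperm protein score, against 488 for independent lists, and 1837 were lower with the vitellogenin score, against 617. Probes higher with the vitellogenin score made up 400 of them, against 790, and probes lower with the major sperm protein score 204, against 677. Both scores were measured on the same arrays as the probes, and these overlaps were not tested. The lists are not separate, as 2980 probes were both higher with the major sperm protein score and lower with the vitellogenin score, against 653 for independent lists. The overlaps were not computed without batch 3 worms 2, 17 and 19, where 1960 probes in place of 4465 were higher with the major sperm protein score. Among highly variable probes in an overlapping pair that passed, the 25 with the highest ratios (4.02 to 6.00) held 0 members of the families as defined here. The collagen rule needs at least 5 glycines in a row of triplets, so it misses collagen probes with a shorter run. The first-ranked probe, CE0208_34468, translates to a stretch ending in GLPGPA, a shorter glycine repeat. The 0 thus does not show that collagens were absent among them. Of these 25, 10 were higher and 0 lower with the major sperm protein score, and 2 were higher and 15 lower with the vitellogenin score. Some of the 25 overlap each other in sequence.

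Most muscle myosin probes were higher with the collagen-repeat score. With slide means removed, 0 probes of any kind passed after adjustment over all probes, and myosin probes were not counted alone there. The correlation of the collagen-repeat and myosin scores kept its sign and stayed past the threshold under all 13 alternatives, slide included (r = 0.50 to 0.83). The limma test gave 5 of 7 myosin probes higher and 0 lower (6 and 0 when adjusted over the list alone), with a median slope of 0.65. Of the 61 histone probes, 13 were higher (23 when adjusted over the list alone), and 0 vitellogenin and 0 major sperm protein probes passed in limma, where 1 and 3 had an unadjusted p under 0.05 (1 vitellogenin probe passed when adjusted over the list alone). Over all probes, 1634 were higher and 591 lower, together 2225 of 38542, while the highest of 100 shuffles gave 1. Those shuffles exchanged worms between slides and so do not allow for slide differences. With slide means removed the limma count was 0 (5745 probes at an unadjusted p under 0.05), and with normexp background correction it was 3456, 3381 of them higher; removing the trend over probe GC content gave 1300 higher and 2058 lower.

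The batches differed in the signal of several families, among them sperm, yolk and collagen-repeat probes, beyond the shift of other probes of like brightness. All 26 major sperm protein probes were higher in batch 2 than in batch 1, with a median difference of 1.11 log2 units, and all 26 were higher in batch 3 than in batch 1, by 1.56. Probe lists matched on mean signal shifted by -0.48 and -0.21, and the family lay above all 10000 of them in both comparisons. Ranks against such lists take no account of the correlation between members of a family. All 7 vitellogenin probes were lower in batch 2 than in batch 1, by a median of -1.01 (matched lists -0.49, all of them above the family), and all 7 higher in batch 3 than in batch 2, by 1.26 (matched lists 0.23, family at percentile 99.99). Of the 50 collagen-repeat probes, 46 were higher in batch 3 than in batch 1, with a median difference of 3.11 (matched lists 0.98, family at percentile 99.99), and 48 higher in batch 3 than in batch 2, by 2.98 (matched lists 0.63, all of them below the family). Of these 50 probes, 31 and 33 were well above background on all arrays of batches 1 and 2, against 48 in batch 3. Control spots foreign to the worm were well above background on a share of 0.248, 0.372 and 0.79 in batches 1, 2 and 3. Hairpin control spots stood at 0.00654, 0.0103 and 0.00588. Whether RNA matching the foreign-sequence spots was added is not known here. Dim signal without a worm target in batch 3 is thus neither shown nor ruled out for collagen. Each of these directions held under normexp, quantile normalization, the authors' value table and scaling to the actin, tubulin, ubiquitin and GAPDH probes, with 0.83 to 1.66 for sperm in batch 3 against batch 1 1.07 to 2.38 for collagen, and, for yolk, -1.02 to -0.568 in batch 2 against batch 1 and 0.446 to 1.26 in batch 3 against batch 2. Histone probes were higher in batch 3 than in batch 2 by a median of 0.98 (matched lists 0.18, all of them below the family; 0.169 to 0.945 under those alternatives). They were higher than in batch 1 by 0.31 (matched lists -0.21, all of them below the family), which turned to -0.42 with reference scaling. Ribosomal protein probes lay at percentile 99.31 of matched lists in batch 3 against batch 2 (0.54) and the actin, tubulin, ubiquitin and GAPDH probes at 99.36 in batch 3 against batch 1 (0.45). Both differences turned negative under quantile normalization (-0.144 and -0.028) and reference scaling (-0.271 and -0.288). The former was also negative in the authors' value table (-0.181). The limma F-test over the 3 batch means was passed by all 26 major sperm protein, 7 vitellogenin, 50 collagen-repeat and 18 ribosomal protein probes, 57 of 61 histone, 32 of 35 actin, tubulin, ubiquitin and GAPDH and 4 of 7 myosin probes.

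Over all probes, 34841 of 38592 (90.3%) differed between the 3 batches in limma. Batch 3 differed from batch 1 at 31340 probes, of which 21716 were higher, and the median difference of all probes was 0.81; it differed from batch 2 at 27177 probes, of which 20618 were higher, with a median of 0.50. Batches 2 and 1 differed at 19500 probes, 8805 higher and 10695 lower in batch 2, with a median of -0.11. Each batch was scanned on days of its own and each slide lay in 1 batch, so batch, scan and slide group cannot be told apart. With slide as a random block (correlation 0.225) the limma count was 32989, and with the array's raw signal level and share of spots well above background as covariates it was 21001.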

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

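The test on slides within batches and the alternatives that remove the GC trend or leave out worms were chosen only after the results they bear on had been seen, as were the comparisons of the first component with its form under signal covariates or without slide means, their bounds, and its share within slides. Single outlying worms were tested for only in batch 1 (9 worms), as the test used is limited to groups of at most 10, so batches 2 and 3 were not tested. There 14 measurements were tested at both ends (family levels, components, array signal), and none of the 28 gaps passed; chance passes about 1 in 20.

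Control spots with E1A in their name, of sequences foreign to the worm, gave signal, and no comparison used them. Whether RNA matching these spots was added to the samples is not known here, so their signal may come from a matching target. A mean share of 0.79 of these spots was well above background in batch 3 (0.263 to 0.994 over arrays), against 0.248 in batch 1 and 0.372 in batch 2. Hairpin control spots were well above background on a share of 0.00588, 0.00654 and 0.0103 in the same order of batches. The foreign-sequence spots differed in level too. Their median signal was 24.4 in batch 3, 3.25 in batch 1 and 7.79 in batch 2. The same batch had nearly all worm probes well above background. A lower detection limit is argued against: on the median batch 3 array a share of 0.983 of worm spots exceeded the highest detection limit of the arrays of batches 1 and 2, where the median shares were 0.735 and 0.794. Signal at probes without a worm target stays open, since the share of 0.79 lay between the bounds of 0.9 and 0.5 set for it. That share measures such signal only if no matching RNA was added. Some of the dim signal in batch 3, collagen-repeat probes included, may not come from the named transcript. No biological explanation was tested, as batch is the only label.

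The count of 34841 probes that differed between batches was reached by 1 of 100 splits of the worms into groups of the same sizes, the real one. The highest other split gave 3510, so random splits of single worms did not give such a count. These splits break up the slides, so they do not measure chance differences between groups of slides. With slide as a random block the limma count was 32989. Between slides of the same batch 8381 probes differed in limma, again reached by 1 of 100 splits, the real one, with 2489 in the highest other, so worms that shared a slide resembled each other more than chance gives. The labels do not say whether worms on a slide were also grown, amplified or labelled together, and these cannot be told apart here.

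Worms spread along a first component that held 23.7% of the within-batch variance. Array signal strength as the whole cause is argued against, while a part in it stays open: the larger of its correlations with the raw signal level and the share of spots well above background was -0.20 ± 0.11 (jackknife SE), within that spread of the bound of 0.3, but with both taken out as covariates the component had r = 0.92 ± 0.033 (jackknife SE) with the original, yet r with the raw signal level was 0.53 without batch 3 (adjusted permutation p = 0.0457) and 0.35 with normexp (0.0531), and r with the share was -0.35 without batch 2 (0.0441) and -0.51 within batch 1. An array-wide GC trend and probe GC content are argued against as the whole cause: with the trend removed the component had r = 0.998 with the original, while the share of collagen-associated probes that were higher went from 73.4% to 38.7%, and rho across probes was 0.12, between the bounds set for it. Slide differences as the whole cause are argued against by r = 0.742 ± 0.079 (jackknife SE) with the original once slide means were removed, when the component still held 24.3%. A part stays open. With slide means removed r was 0.48 with the vitellogenin score and 0.57 ± 0.10 (jackknife SE) in size with the major sperm protein score (adjusted permutation p = 0.0087 for both). These values lay either side of the bound of 0.5 and within that spread of it. With the histone score r was 0.63 (adjusted permutation p = 0.0018). The share of the component's variance within slides was 55.1 ± 16.6%, with 73.7% expected if slide had no bearing. Without batch 3 worms 2, 17 and 19 it was 67.2 ± 22.1% against 71.4%. Probes associated with vitellogenin in limma fell to 1463, with 9468 at an unadjusted p under 0.05 in place of 16476. Those associated with major sperm protein numbered 7721 in place of 10656. The amplification of each worm's cDNA was not measured separately.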

How the results depend on the processing

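No paired analysis was possible because the replicate numbers are only names in accession order. Across 41 results, 425 of 485 values under an alternative kept their direction and stayed on the same side of the threshold or close to the main value, and 60 did not, 4 of them with the sign reversed. The cause of the changes below was not tested, except where fewer probes, pairs or worms entered. The settings on reference scaling, GC trend, 40-base overlaps and leaving out 3 worms were chosen after seeing the data. The number of highly variable probes was 3141 to 5088 over settings and 1707 at a ratio threshold of 2. Concordant pairs numbered 1603 with probes well above background on all arrays, 1227 with overlaps of at least 40 bases and 41 with the extremes of 3 or more overlapping probes, each from fewer pairs. The mean rho between batches was 0.39, and 0.347 with normexp, 0.347 with quantile normalization, 0.333 in the authors' value table and 0.351 without batch 2. The families that varied beyond matched lists did so under every setting run, and under reference scaling the ribosomal protein probes varied less than matched ones (ratio 0.81).

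Under quantile normalization the mean pairwise r was 0.038 for ribosome and 0.074 for actin, tubulin, ubiquitin and GAPDH probes, and the scores had r = 0.025 (histone and ribosome), 0.31 (histone and reference) and -0.098 (ribosome and reference). In the authors' value table these were 0.038, 0.058, -0.084, 0.25 and -0.15. Under scaling to the reference probes the mean pairwise r was 0.42 for myosin and -0.0087 for the reference probes themselves, which that scaling centres, and with the GC trend removed it was 0.094 for the reference probes, not past the threshold. Correlated pairs of scores numbered 5, and 8 by Spearman correlation, 11 with array quality covariates and 12 without batch 3. Pairs whose slopes differed between batches numbered 0, and 1 with quantile normalization, 2 without batch 1 and 1 without batch 2.

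Probes associated with the vitellogenin score numbered 1463 with slide means removed, 1928 without batch 3 and 6616 without batch 3 worms 2, 17 and 19, and with the major sperm protein score 1195 and 2373 in the last 2 settings. For the collagen-repeat score the counts were 3456 with normexp, 1257 with array quality covariates, 0 with slide means removed (limma; 5745 at an unadjusted p under 0.05), 1298 without batch 1, 878 without batch 2 and 3358 with the GC trend removed. The share of associated probes that were higher was 56.1% for vitellogenin, and 67.9% with reference scaling, 68.6% with the GC trend removed, 43.7% with slide means removed and 46.6% without batch 3. For collagen repeat it was 73.4%, and 97.8% with normexp, 63.1% with quantile normalization, 84.2% without batch 2, 58.8% over probes well above background on all arrays and 38.7% with the GC trend removed. The first component held 31.1% with normexp, 29.99% over probes well above background on all arrays and 17.2% without 3 worms. Its r with the major sperm protein score was -0.36 with normexp, -0.10 without batch 3 and -0.17 without 3 worms, none past the threshold, and with the collagen-repeat score it passed at -0.38 with normexp and 0.53 without batch 3. Probes differing between batches numbered 22646 when well above background on all arrays, 21001 with quality covariates and 18554 without batch 3. Not run were the mean over probes of a gene, the gene lists, the oocyte and eggshell score and the housekeeping list, which need gene names, and a score from members never saturated, since no worm spot was saturated. Fewer spots were well above background in batches 1 and 2 than in batch 3.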

Other observations

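The leaving out of 3 worms was chosen only after the result was seen. Batch 3 worms 2, 17 and 19, with the lowest sperm signal of their batch, had vitellogenin levels of 5.35, 6.00 and 5.87, inside the range of 3.15 to 6.04 of the other 17 worms of batch 3. Their histone levels were 3.81, 4.62 and 4.29, against 3.51 to 4.33 in the others, and their myosin levels 0.84, 1.44 and 1.04, against 0.07 to 2.19. Their collagen-repeat levels were -1.14, -0.54 and -0.69, against -1.30 to 0.16. Their ribosomal protein levels were 4.13, 4.68 and 4.46, against 4.19 to 5.03. No test was run on these worms as a group.

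Families too small to test had these mean log2 levels in batches 1, 2 and 3. The 4 homeodomain probes, of transcription factors, stood at -5.21, -4.93 and -3.90, the 3 heat shock chaperone probes at 4.48, 3.93 and 4.12, and the ATP synthase beta probe, of mitochondria, at 5.03, 4.71 and 5.21. All 8 of these probes passed the limma F-test between batches.

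A hypothesis for the first component is that worms of one nominal age differed in developmental progress. Sperm are made before oocytes in the hermaphrodite and yolk follows at adulthood, so a worm further along may have more yolk and less sperm transcript. The 2 scores themselves were not correlated at the threshold (r = -0.28, adjusted permutation p = 0.234), with r = 0.20 within batch 2 and -0.065 with slide means removed. Of the vitellogenin, major sperm protein and collagen-repeat scores, 2 were correlated with the component after adjustment, as set out for this hypothesis before the component was compared with them (r = 0.65 and -0.59; collagen repeat -0.06). The collagen-repeat members moved together weakly (mean pairwise r 0.20), so their score does not speak for every collagen. Without batch 3 worms 2, 17 and 19, and with the component taken anew, the major sperm protein score had r = -0.17 (adjusted permutation p = 0.55). The vitellogenin score was then the only one of the 3 still related, with r = 0.63 (adjusted permutation p = 0.00045). For its sperm part the hypothesis rests on few worms, and feeding, body size or RNA amount, none of them in the labels, were not tested as alternatives.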
